A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

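Total RNA (250 ng) from each of 18 batch cultures was labelled with biotin and hybridised to Affymetrix yeast arrays, per the labels' protocols. Cultures of 500 ml in a buffered synthetic medium were kept at 30 °C and 600 rpm and sampled at an optical density of about 1. The deposited values are on a log2 scale, as read from their range of 4.85 to 12.8, and 1 value was given per probe set and array. Summarization with PLIER and use of R 2.10.1 are named in the submitters' processing notes. The background correction, the normalization and the base of the logarithm are not given in the sources used here, so fold changes rest on the reading of the scale as log2. Each array entered as its own replicate, and the labels call the 3 arrays of a group biological replicates.

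Gene names came from the platform's annotation table and were updated through a current gene table, which changed 12 symbols. Of 10928 probe sets, 7244 had 1 gene, 1 had several and 3683 had none in that table. The 5498 S. cerevisiae probe sets with 1 gene, for 5449 genes, were tested, and 1747 S. pombe probe sets served to set the background. The background level was the 95th percentile of the S. pombe probe sets, 5.56 over all arrays and 5.55 to 5.60 by array, and 5032 tested probe sets had a mean above it. Where any group on the lower side of a comparison had a mean under background, a fold is given as a lower bound (at least). It is the ratio of the brighter side's mean to the lower side's mean after values under an array's background level were raised to that level. That any dim group, and not only all of them, makes a fold a lower bound was decided after the results were seen. No fold is given where both sides were at background. Probe sets that match several near-identical genes are named as shared. No genomic coordinates are given, since no genome build is named for the array.

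A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes), with 12 residual and 3.10 prior degrees of freedom, so that all groups share 1 estimate of the spread. The 13 contrasts were the effect of anaerobic growth in each strain and in the mean of the strains, the 6 differences between strains within a condition, and the 3 interactions. P-values were two-sided and adjusted by the method of Benjamini and Hochberg over all tested probe sets of a contrast, with a threshold of 0.05. They were adjusted again over each list alone. For 37 lists of genes, camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives, and fry asks only whether a list's genes move, on balance, in 1 direction. With the estimated correlation 24 of 163 list calls in 10 contrasts held.

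The groups, lists, tests, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 10 largest rises and falls past the threshold in the mean oxygen effect with the same sign in all strains. It took the 5 largest each way in a strain comparison whose arrays did not overlap between groups, which chance gives for 10% of probe sets, and the 3 largest each way in an interaction. For a list that is described it took up to 4 members with the smallest p, and some genes of the plasmid, host, endoplasmic reticulum and oxygen response were always taken. TEF1 had no probe set of its own. Alternatives were quantile normalization, centring on array medians, a filter on dim probe sets, eBayes with trend and robust settings, fits to only the groups compared, the replicate number as a block, and leaving out each array. Leaving out the array labelled AAP aerobic replicate 3 for all contrasts, and removing a trend on coding length (a loess curve with span 0.5 on each array's deviations), were added after the data were seen. Of the gene models used for length, 96.8% had lengths that are multiples of 3.

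The labels do not say that a replicate number marks a shared batch. In the data all 3 same-number pairs correlated above 0.1 in their deviations from the group means for NC with AAC (0.126, 0.233 and 0.326) and for AAC with AAP (0.168, 0.249 and 0.456) in aerobic cultures, and in no other comparison of 2 groups tested here. The highest values were those of NC with AAC in anaerobic cultures, 0.645 and 0.459 for replicates 1 and 3, beside -0.0239 for replicate 2. Deviations within a group sum to 0, so the 3 values are not independent. Those of aerobic AAP include the array labelled AAP aerobic replicate 3, so the values for AAC with AAP need not mark a shared batch. Values with the block are given for the 2 aerobic comparisons named first where they change a call or move a count by more than 1.5 times. A block with the length trend removed was added for them after the data were seen.

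The procedure was tested on simulated data, and the results were read from the comparison of AAC with NC in anaerobic cultures. Noise was drawn as independent normal values for each probe set and array, with no correlation between genes and no array set apart. The real arrays need not behave so, and the shares below are not error rates of the real calls. Of changed probe sets, 54.0% were called at a log2 change of 0.25, 94.0% at 0.5 and 100.0% at 1 and at 2, and 6.45% of calls were unchanged probe sets. A pseudocount was not used, because the values are already logarithms.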

Results

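Transcript levels were measured in 3 strains of Saccharomyces cerevisiae grown with or without oxygen, on 18 Affymetrix yeast genome arrays. The host was a laboratory strain whose own triose phosphate isomerase gene, TPI1, is deleted, so that growth on glucose depends on the isomerase gene of fission yeast (tpi1, or POT1) carried on a multicopy plasmid. Strain NC held an empty plasmid. In AAC, labelled a high producer, the TPI1 promoter drove a secreted amylase behind the alpha factor leader. In AAP, labelled a lower producer, the TEF1 promoter drove the same kind of cassette. Each strain was sampled early in glucose growth in aerobic and in anaerobic batch culture, which gave 6 groups of 3 biological replicates. Array medians over the 5498 S. cerevisiae probe sets tested ranged from 7.08 to 7.13 log2 units, and 90.0% to 91.7% of these probe sets lay above the background level of their array. The number of arrays limits the precision of every value.

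The fission yeast tpi1 probe set separated the strains. Its mean log2 signal in aerobic cultures was 6.24 ± 0.0991 (SD, n = 3) in NC and 9.23 ± 0.229 (SD, n = 3) in AAC, and in anaerobic cultures it was 6.71 ± 0.498 (SD, n = 3) in NC, 9.92 ± 0.509 (SD, n = 3) in AAC and 12.45 ± 0.0311 (SD, n = 3) in AAP. No test here explained the low level in NC, and differences from NC in this signal stay open to that extent. The strains thus differed in the signal of the isomerase gene as well as in the amylase cassette. Comparisons between strains cannot tell these apart. The host's own TPI1 stayed at background in all 6 groups, at 5.34 to 5.47 log2 units. The array labelled AAP aerobic replicate 3 read 9.24 for fission yeast tpi1, against 12.42 and 12.38 in AAP aerobic replicates 1 and 2, and its correlation with the AAC aerobic arrays (mean Pearson r across genes 0.993) was above that with the other AAP aerobic arrays (0.978). For DET1, a gene beside TPI1 that encodes an acid phosphatase, that array read 11.28 against 7.80 and 7.61 in AAP aerobic replicates 1 and 2. For HES1, which encodes an oxysterol-binding protein, it read 9.24 against 5.55 and 5.54. Counts of changed probe sets that use this array, and the genes and lists of the strain comparisons with the aerobic AAP group, are given with their values without it. Leaving it out was planned for counts of the contrasts that use it, as for every array, and was chosen after the data were seen for the gene lists and the other contrasts.

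**Figure D1:**
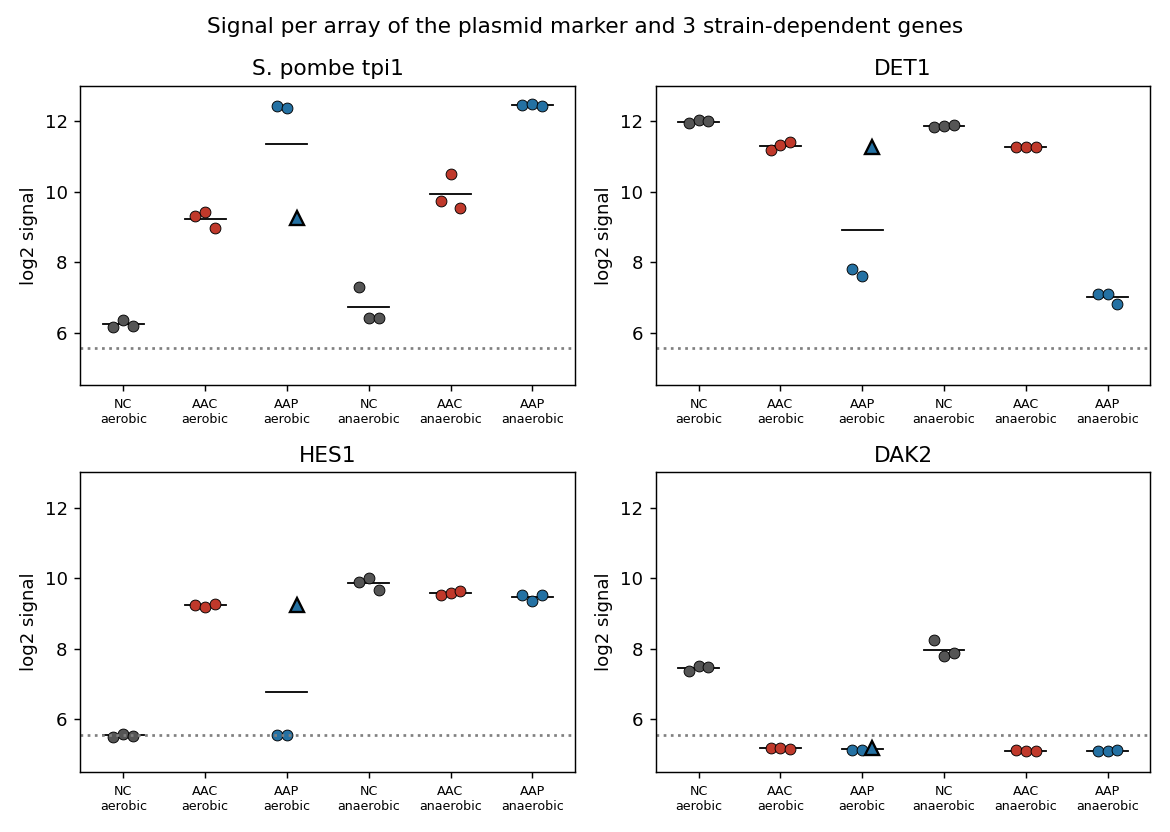
Log2 signal of each array (points, 3 per group) for fission yeast tpi1, DET1, HES1 and DAK2 by strain and condition, with group means as bars and the background level as a dotted line. The array labelled AAP aerobic replicate 3 (triangle) reads 9.24 for tpi1, 11.28 for DET1 and 9.24 for HES1, beside the AAC aerobic arrays.

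Anaerobic growth raised transcripts of cell wall mannoproteins and of other hypoxic genes in all 3 strains. TIR1, a cell wall mannoprotein gene, rose 81.0-fold on average over the strains (log2 difference 6.34 ± 0.0223, SE), from 5.76 ± 0.0459 (SD, n = 3) to 12.12 ± 0.0449 (SD, n = 3) in NC. DAN1 and TIR4, of the same class, rose at least 62.2-fold and at least 65.3-fold, DAN1 from background in all 3 strains and TIR4 from background in AAC and just above it in NC and AAP. ANB1, the hypoxic form of translation factor eIF5A, rose 28.5-fold, and HEM13, coproporphyrinogen oxidase of heme synthesis, rose 15.9-fold. Transcripts of the respiratory chain went the other way: CYC1, the main cytochrome c gene, fell at least 51.6-fold, the external NADH dehydrogenase gene NDE1 fell 18.9-fold (log2 difference -4.24 ± 0.0450, SE) and cytochrome c1 (CYT1) fell by 3.91 log2 units. The other large rises were TIR3 (35.4-fold), PAU3 (at least 26.9-fold), HUG1 (at least 20.0-fold), PBI1 (at least 12.4-fold) and PAU14 (12.6-fold). The PAU3 and PAU14 probe sets are shared by several near-identical genes and do not tell them apart. Further large falls were those of YER053C-A (at least 12.5-fold), the cytochrome oxidase subunits COX12 (8.64-fold), COX7 (8.09-fold) and COX5A (8.08-fold), the heme oxygenase HMX1 (7.84-fold), the Rieske protein RIP1 (7.77-fold) and the lipid droplet protein PLN1 (7.73-fold).

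By gene group, all 6 DAN/TIR mannoprotein genes rose (camera adjusted p = 3.89e-09), and all 6 when adjusted over the list alone. All 13 measured seripauperin genes of the 24 listed rose, as they did adjusted over the list alone (camera adjusted p = 7.60e-09, and adjusted p = 0.128 with an estimated correlation). Of 8 genes repressed by Rox1, the heme-dependent repressor of hypoxic genes, 7 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.000359). AAC3 rose 8.70-fold and COX5B, the hypoxic counterpart of COX5A, 3.03-fold. In sterol uptake and esterification 8 of 11 genes rose and 2 fell, the same adjusted over the list alone, among the rises AUS1 (11.3-fold) and UPC2 (4.14-fold). That list had camera adjusted p = 0.00216, and adjusted p = 0.173 with an estimated correlation. All 22 respiratory chain genes fell, also adjusted over the list alone (camera adjusted p = 1.36e-20), with a median log2 difference of -2.35. All 15 ATP synthase genes fell, INH1 by 5.79-fold among them (camera adjusted p = 6.18e-12), and so did 67 of 68 mitochondrial ribosomal protein genes (camera adjusted p = 7.71e-25). Both counts were the same adjusted over the list alone. All 12 genes of the TCA cycle fell, also adjusted over the list alone, KGD2 by 2.18-fold (camera adjusted p = 7.60e-09, and adjusted p = 0.0680 with an estimated correlation). In amino acid biosynthesis 31 of 40 measured genes fell and 7 rose, 31 and 8 adjusted over the list alone, ARG1 falling 2.83-fold (camera adjusted p = 5.48e-06, and adjusted p = 0.194 with an estimated correlation).

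The secretory pathway moved by less. Of 18 genes for protein folding in the endoplasmic reticulum and the unfolded protein response, 14 rose and 1 fell, the same adjusted over the list alone, with a median log2 difference of 0.31 (camera adjusted p = 0.00233, and adjusted p = 0.374 with an estimated correlation). The disulfide isomerase homolog EUG1 rose 4.39-fold, the chaperone KAR2 by 0.38 log2 units, the disulfide isomerase PDI1 1.16-fold and the oxidase ERO1 1.22-fold, while HAC1, the transcription factor gene of the response, fell by 0.55 log2 units. By strain, KAR2, PDI1 and ERO1 passed in NC alone with all arrays as labelled (log2 differences 0.81, 0.40 and 0.91). In AAC and AAP they had 0.26 and 0.06 for KAR2, 0.10 and 0.15 for PDI1, and 0.28 and -0.33 for ERO1, whose mean also missed the threshold when single arrays were left out (adjusted p = 0.0641 without AAC aerobic replicate 1). The AAP values include the array labelled AAP aerobic replicate 3. For ERO1 it read 9.70 log2 units, against 9.31 and 8.56 in AAP aerobic replicates 1 and 2 and 8.75 to 8.96 in anaerobic AAP. For KAR2 it read 11.315, against 11.18 and 10.72 in those replicates and 11.04 to 11.25 in anaerobic AAP. For PDI1 it read 10.93, against 10.92 and 10.79. HAC1 passed in AAP alone with all arrays as labelled (-0.99, against -0.32 in NC and -0.33 in AAC). In vesicle transport between endoplasmic reticulum and Golgi 20 of 29 genes rose and 1 fell (21 and 1 adjusted over the list alone), ERV29 by 1.42-fold (camera adjusted p = 0.00118). Among 21 genes of translocation and signal peptide processing 14 rose, 15 adjusted over the list alone, SEC66 by 0.58 log2 units (camera adjusted p = 0.00118, and adjusted p = 0.161 with an estimated correlation). FRD1, a fumarate reductase, rose 3.32-fold and the other fumarate reductase gene, OSM1, 1.22-fold. CYC7, the minor cytochrome c gene, rose 1.24-fold in the mean and passed in AAC alone (log2 difference 0.67, against 0.38 with adjusted p = 0.0515 in NC and -0.12 with adjusted p = 0.586 in AAP). ERV29 and SEC66 passed in NC and AAC and not in AAP. The passes by strain given here are those of the fit to all 18 arrays as labelled. A gene that passes in 1 strain and not in another need not differ between them.

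In the mean over strains limma called 3386 probe sets, 1716 higher and 1670 lower in anaerobic cultures, a balance that turned with arrays centred on their medians (1659 and 1772) and without the array labelled AAP aerobic replicate 3 (1797 and 1873 of 3670). Of the 3386, 103 rose and 122 fell by 2-fold or more. All 20 genes with the largest changes kept their direction and passed the threshold without that array. Of the 18 lists called for the mean effect with the preset correlation, 6 held with an estimated correlation.

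**Figure D2:**
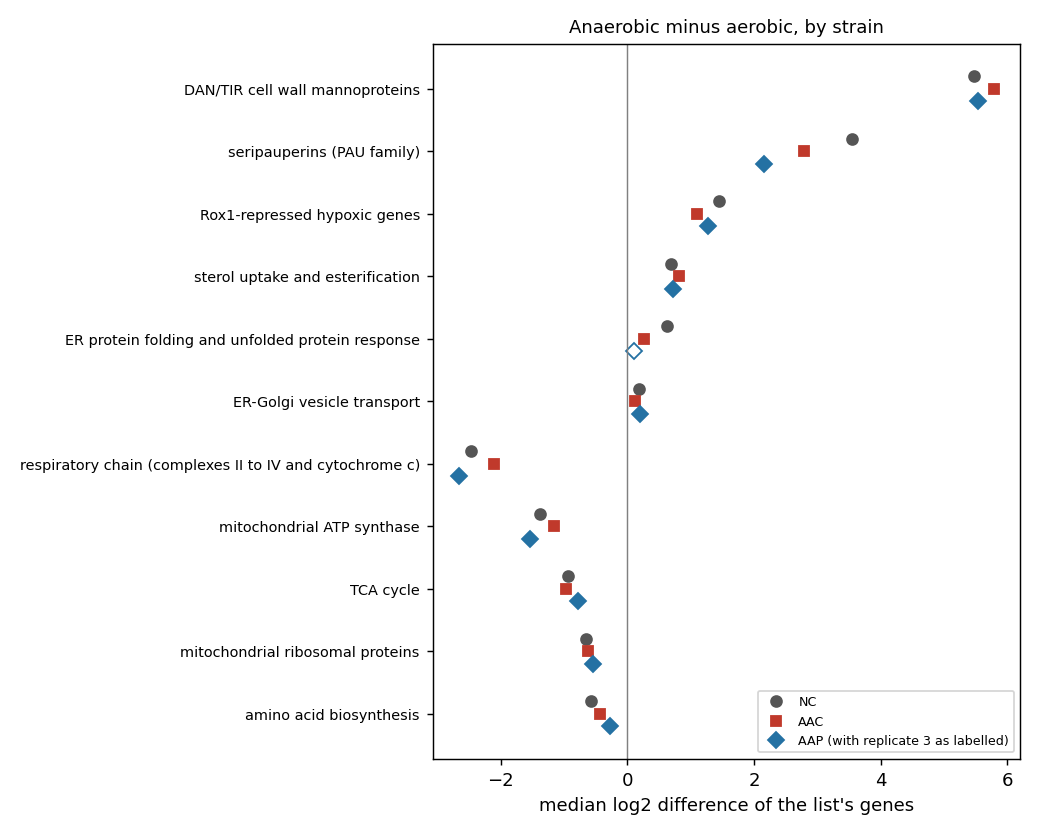
Median log2 difference, anaerobic minus aerobic, over the genes of 11 lists in NC, AAC and AAP. Filled symbols passed the camera test with the preset correlation; the respiratory chain medians were -2.48 in NC, -2.11 in AAC and -2.66 in AAP.

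Strain by strain, 3783 probe sets were called for oxygen in at least 1 strain, and 53 of them in opposite directions in 2 strains. Respiratory chain transcripts fell for all 22 genes in NC, AAC and AAP, also adjusted over the list alone (camera adjusted p = 1.91e-21, 8.58e-23 and 5.44e-32). DAN/TIR transcripts rose for all 6, also adjusted over the list alone (1.80e-11, 9.41e-12 and 8.63e-13), and both counts were the same without the array labelled AAP aerobic replicate 3. ER folding genes rose for 14 of 18 in NC, 14 with 1 fall adjusted over the list alone (camera adjusted p = 2.64e-05, and adjusted p = 0.197 with an estimated correlation), KAR2 by 1.75-fold and ERO1 by 1.88-fold. In AAC 8 of these 18 rose, 9 with 1 fall adjusted over the list alone (camera adjusted p = 0.0178, and adjusted p = 0.519 with an estimated correlation), and in AAP 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.331; 5 and 1 without the array). Ribosome biogenesis transcripts fell for 34 of 35 genes in NC, also adjusted over the list alone (camera adjusted p = 1.58e-07, and adjusted p = 0.375 with an estimated correlation) and for 16 in AAC, also adjusted over the list alone (camera adjusted p = 0.00918, and adjusted p = 0.707 with an estimated correlation). In AAP 1 of them rose and 1 fell, and limma called 0 adjusted over the list alone, with 6 at an unadjusted p under 0.05 (camera adjusted p = 0.999). Without the array 12 fell (camera adjusted p = 0.0207). limma called 2763 probe sets in NC (1222 higher, 1541 lower, and 1492 and 1404 with the trend on coding length removed), 2445 in AAC (1193 higher, 1252 lower) and 2110 in AAP (1163 higher, 947 lower, and 998 and 1115 with median centring; 2303 without the array). The AAC balance turned to 1315 and 1217 with quantile normalization, 1260 and 1238 with median centring, 1235 and 1211 with the length trend removed and 1235 and 1169 without AAC anaerobic replicate 3. Of the 3783, those higher in all 3 strains were 562 and those lower in all 3 were 687, against 56.1 and 60.4 for independent lists of these sizes (684 and 863 without the array). The effects correlated across genes with Pearson r of 0.918 between NC and AAC, 0.869 between NC and AAP and 0.912 between AAC and AAP, where genes are not independent replicates.

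AAC was compared with NC in aerobic cultures, with the amylase under the TPI1 promoter in AAC and an empty plasmid in NC. What differed can go with amylase production or with the fission yeast tpi1 signal, 2.99 log2 units higher in AAC. The design cannot tell these apart. HES1 was at background in NC, at 5.53 ± 0.0430 (SD, n = 3), and at 9.23 ± 0.0391 (SD, n = 3) in AAC, at least 12.6-fold higher. The phosphate-responsive acid phosphatase PHO5 rose 4.78-fold (log2 difference 2.26 ± 0.411, SE), the secreted glycoprotein YGP1 3.99-fold and the phosphate transporter PHO84 3.73-fold. DAK2, a dihydroxyacetone kinase, fell at least 3.67-fold to background. Also among the largest changes, YBL100W-A, a transposon gene on a shared probe set, rose 6.31-fold, and ZPS1 (2.95-fold), the mannoprotein TIR3 (log2 difference -1.07), the RNA helicase DBP2 (1.57-fold) and the nucleolar NOP13 (1.55-fold) fell. DBP2 missed the threshold with quantile normalization (log2 difference -0.61, adjusted p = 0.0539). In the ER folding list 11 of 18 genes rose and none fell, also adjusted over the list alone: ERO1 2.09-fold, SIL1 1.78-fold, KAR2 1.71-fold and PDI1 1.37-fold (camera adjusted p = 1.25e-07, and adjusted p = 0.219 with an estimated correlation). HAC1 did not pass (log2 difference 0.21, adjusted p = 0.265).

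Of 22 heat shock and general stress genes 19 rose, also adjusted over the list alone, HSP12 by 2.66-fold and HSP42 by 1.65-fold (camera adjusted p = 4.66e-13, and adjusted p = 0.170 with an estimated correlation). Glycolysis and ethanol formation had 11 of 20 genes higher, 16 adjusted over the list alone, with GLK1 at 2.37-fold and TDH1 at 2.70-fold (camera adjusted p = 5.51e-09, and adjusted p = 0.170 with an estimated correlation). In the phosphate regulon 11 of 15 rose, also adjusted over the list alone (camera adjusted p = 3.69e-07, and adjusted p = 0.263 with an estimated correlation), and in glycerol metabolism 6 of 10, 8 adjusted over the list alone, GPP2 by 2.31-fold and GPD1 by 1.87-fold (camera adjusted p = 6.66e-07, and adjusted p = 0.170 with an estimated correlation). Cytosolic ribosomal protein genes fell for 59 of 128, 71 adjusted over the list alone, by small amounts such as 1.29-fold for RPS9B (camera adjusted p = 1.34e-15, and adjusted p = 0.263 with an estimated correlation). Ribosome biogenesis fell for 19 of 35, 32 adjusted over the list alone, KRR1 by 1.39-fold (camera adjusted p = 6.18e-11, and adjusted p = 0.289 with an estimated correlation). URA3, of pyrimidine synthesis, fell by 0.46 log2 units, and the probe set shared by TEF1 and TEF2 did not pass (log2 difference 0.01, adjusted p = 0.909). In all, 1067 probe sets passed, 518 higher and 549 lower, with 36 and 3 of them by 2-fold or more. That balance turned to 510 and 497 with quantile normalization, to 728 and 524 with the length trend removed (743 and 560 with the replicate number as a block as well), to 544 each with trend and robust settings, and to more higher than lower without any 1 of the 6 NC and AAC aerobic arrays. The count was 1650 without the array labelled AAP aerobic replicate 3, which enters only through the shared spread, 554, 559 and 599 without NC aerobic replicates 1, 2 and 3, 687 and 580 without AAC aerobic replicates 1 and 3, and 2079 in a fit to only the arrays of these 2 groups.

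Few genes passed between AAP and NC in aerobic cultures with all arrays as labelled. DAK2 fell at least 3.63-fold to background, and at least 3.65-fold without the array labelled AAP aerobic replicate 3. HSP12, a small stress protein, rose 1.94-fold (log2 difference 0.96 ± 0.133, SE; 0.78 without the array labelled AAP aerobic replicate 3). The glycerol 3-phosphate dehydrogenase GPD1 rose 1.56-fold (log2 difference 0.64, and 0.56 without the array), hexokinase HXK1 1.78-fold (0.83, and 1.00 without it) and RTC3 also rose (0.85, and 0.68 without it). TMA10 rose 1.98-fold with all arrays and no longer passed without that array (log2 difference 0.75, adjusted p = 0.0565). The aquaporin AQY2 fell by 0.49 log2 units (-0.52 without the array) and LEU9, of leucine synthesis, by 0.36 (log2 difference -0.35, adjusted p = 0.0569 without it). LEU9 also missed the threshold with quantile normalization, median centring, trend and robust settings and the length trend removed, and TMA10 with quantile normalization and median centring. In ER folding limma passed 0 of 18 genes, 11 adjusted over the list alone and 11 at an unadjusted p under 0.05, while the list as a whole stood higher (camera adjusted p = 1.69e-09, and adjusted p = 0.151 with an estimated correlation; 1.96e-06 without the array). KAR2 had a log2 difference of 0.50 (adjusted p = 0.0840), and 0.38 without the array. The 2 AAP aerobic arrays then left differed from each other. Replicate 1 stood above NC for ERO1 (9.31, against 8.49 to 8.62 in NC) and PDI1 (10.92, against 10.61 to 10.80), and replicate 2 did not (8.56 and 10.79). For KAR2 both stood above NC (11.18 and 10.72, against 10.56 to 10.58). Of 40 amino acid biosynthesis genes limma passed 0, with 20 lower and 1 higher adjusted over the list alone and 25 at an unadjusted p under 0.05 (camera adjusted p = 8.69e-12, and adjusted p = 0.151 with an estimated correlation; 2.17e-23 and 3 lower without the array). limma called 11 probe sets, 8 higher and 3 lower, with 515 at an unadjusted p under 0.05. Without the array labelled AAP aerobic replicate 3 it called 33, 11 higher and 22 lower, DET1 (log2 difference -4.28, adjusted p = 2.33e-14) among them, named after its value was seen, and without AAP aerobic replicate 2 it called 60. Without AAP aerobic replicate 1 or NC aerobic replicates 1, 2 or 3 it called 4, 5, 4 and 4, and fitted to only the arrays of these 2 groups 1, lower in AAP, which ended the calls of all the genes named above but DAK2.

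AAC was also set against AAP in aerobic cultures. YRO2, a plasma membrane protein gene, was 2.68-fold higher in AAC (log2 difference 1.42 ± 0.279, SE; 1.90 without the array labelled AAP aerobic replicate 3). AGX1, alanine glyoxylate aminotransferase, was also higher (log2 difference 1.07, and 1.48 without the array), PDH1 1.82-fold (0.86, and 1.00 without it), the mannoprotein TIP1 1.75-fold (0.81, and 1.14 without it) and the shared probe set of YBL100W-A 4.44-fold (2.15, and 2.36 without it). Lower in AAC were RKI1, ribose 5-phosphate isomerase (log2 difference -0.42, and -0.58 without the array), ALB1 (-0.42, and -0.56), YPL199C (-0.41, and -0.50), NNT1 (-0.41, and -0.56) and YCR087C-A (-0.39, and -0.56). In the TCA cycle 6 of 12 genes were higher, 10 adjusted over the list alone, FUM1 by 0.43 log2 units (0.46 without the array; camera adjusted p = 2.48e-09, and adjusted p = 0.206 with an estimated correlation; 9 genes without the array). Heat shock genes passed for 3 of 22, 14 adjusted over the list alone, HSP78 by 0.72 log2 units (0.98 without the array; camera adjusted p = 1.52e-08, and adjusted p = 0.206 with an estimated correlation; 16 higher and 1 lower without the array). limma called 218 probe sets, 131 higher and 87 lower in AAC, and 0 when fitted to only the arrays of these 2 groups (707 at an unadjusted p under 0.05), which ended the calls of all the genes named above. With the replicate number as a block it called 140, 88 higher and 52 lower, and RKI1 (adjusted p = 0.0550) and YCR087C-A (adjusted p = 0.0535) did not pass. With the length trend removed ALB1 (log2 difference -0.36, adjusted p = 0.0501) and YCR087C-A (-0.34, adjusted p = 0.0790) did not pass. Without the array labelled AAP aerobic replicate 3 it called 1546 (685 higher, 861 lower), HES1 (at least 3.66 log2 units higher in AAC, against background in AAP) and DET1 (log2 difference 3.60) among them, both named after their values were seen. It called 5 without AAP aerobic replicate 1 or 2, and 36, 7 and 34 without AAC aerobic replicates 1, 2 and 3.

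AAC was set against NC in anaerobic cultures as well, where 16 lists were called with the preset correlation and 0 of them held with an estimated one. ULI1, named for its induction in the unfolded protein response, stood at 8.51 ± 0.0878 (SD, n = 3) in AAC and 6.20 ± 0.0819 (SD, n = 3) in NC, a rise of 4.94-fold. YGP1 rose 3.11-fold, RTA1 2.61-fold, the agglutinin subunit AGA1 2.55-fold and the mitochondrial cytochrome b5 reductase MCR1 2.43-fold. Among the largest falls were the biotin transporter VHT1 at 4.07-fold (log2 difference -2.03 ± 0.191, SE), biotin synthase BIO2 at 3.05-fold and BIO3, of the same pathway, at 2.86-fold. DAK2 fell at least 5.28-fold to background and ZPS1 3.54-fold. Respiratory chain genes rose for 18 of 22, 21 adjusted over the list alone, SDH3 by 2.24-fold and COX13 by 1.46-fold (camera adjusted p = 4.49e-15, and adjusted p = 0.111 with an estimated correlation). Heat shock genes rose for 10 of 22, 14 adjusted over the list alone, HSP12 by 2.36-fold and HSP26 by 1.87-fold (camera adjusted p = 1.74e-07, and adjusted p = 0.204 with an estimated correlation).

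Thiamine biosynthesis rose for 6 of 14 measured genes in this comparison, 10 adjusted over the list alone, THI4 by 1.36-fold (camera adjusted p = 2.35e-05, and adjusted p = 0.140 with an estimated correlation). Of 10 glycerol genes 5 rose, also adjusted over the list alone, GPP1 by 1.68-fold (camera adjusted p = 0.000428, and adjusted p = 0.215 with an estimated correlation). In ER folding limma passed 0 of 18 genes, with all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.134), and KAR2 had a log2 difference of 0.22 (adjusted p = 0.192). limma called 660 probe sets, 369 higher and 291 lower, of which 23 and 12 changed by 2-fold or more. The count was 1069 without the array labelled AAP aerobic replicate 3, 1040, 326 and 387 without NC anaerobic replicates 1, 2 and 3, and 360 and 391 without AAC anaerobic replicates 1 and 2.

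Among the S. cerevisiae genes tested, the largest measured log2 difference of AAP from NC in anaerobic cultures was that of DET1. It stood at 6.99 ± 0.165 (SD, n = 3) in AAP and 11.86 ± 0.0315 (SD, n = 3) in NC, 29.2-fold lower in AAP (log2 difference -4.87 ± 0.617, SE). This SE rests on the spread shared by all groups, which the array labelled AAP aerobic replicate 3 widens for DET1. DAK2 fell at least 5.26-fold to background, BIO3 3.65-fold and VHT1 3.52-fold, and the shared probe set of PAU4 3.13-fold. NCE102, an eisosome protein gene, rose 2.23-fold, the cell wall protein CWP1 2.15-fold, the uridine permease FUI1 2.13-fold, malic enzyme MAE1 1.92-fold and ILV3, of branched amino acid synthesis, 1.88-fold. Ribosome biogenesis rose for 25 of 35 genes, 31 adjusted over the list alone, RRP5 by 1.63-fold (camera adjusted p = 4.60e-10, and adjusted p = 0.639 with an estimated correlation). Respiratory chain genes fell for 15 of 22, also adjusted over the list alone, COX4 by 1.53-fold (camera adjusted p = 4.60e-10, and adjusted p = 0.251 with an estimated correlation). ATP synthase genes fell for 10 of 15, 11 adjusted over the list alone, INH1 by 1.44-fold (camera adjusted p = 4.87e-07, and adjusted p = 0.251 with an estimated correlation). Seripauperins, on shared probe sets, fell for 10 of 13, 12 adjusted over the list alone (camera adjusted p = 5.41e-08, and adjusted p = 0.541 with an estimated correlation). In ER folding 5 of 18 fell, also adjusted over the list alone, HAC1 by 1.87-fold and ERO1 by 1.51-fold (camera adjusted p = 0.00360, and adjusted p = 0.639 with an estimated correlation).

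In that comparison of AAP with NC limma called 1153 probe sets, 710 higher and 443 lower. After a trend with coding length was removed 1138 passed, 511 higher and 627 lower. The count was 1749 without the array labelled AAP aerobic replicate 3, 1730, 440 and 493 without NC anaerobic replicates 1, 2 and 3, and 475 and 618 without AAP anaerobic replicates 1 and 2.

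Between AAC and AAP in anaerobic cultures 16 lists were called with the preset correlation, and 1 of them, the respiratory chain, held with an estimated one. DET1 was 19.3-fold higher in AAC (log2 difference 4.27 ± 0.617, SE), ULI1 5.66-fold (log2 difference 2.50 ± 0.120, SE), the flocculin FLO11 3.97-fold, YGP1 3.46-fold and YET2 3.32-fold. For DET1 the SE rests on the shared spread, which the array labelled AAP aerobic replicate 3 widens. The glycine decarboxylase subunits GCV2 (2.96-fold) and GCV1 (1.93-fold), the hexose transporter HXT2 (1.99-fold), aldehyde dehydrogenase ALD6 (1.98-fold) and RRP5 (1.90-fold) were lower in AAC. All 22 respiratory chain genes were higher in AAC, also adjusted over the list alone, COX4 by 1.94-fold and COX13 by 1.92-fold (camera adjusted p = 2.68e-21, and adjusted p = 0.0314 with an estimated correlation). So were 12 of 15 ATP synthase genes, 13 adjusted over the list alone, INH1 by 0.85 log2 units (camera adjusted p = 5.58e-09, and adjusted p = 0.110 with an estimated correlation). In ER folding 9 of 18 were higher, 9 higher and 1 lower adjusted over the list alone: HAC1 2.14-fold, ERO1 2.04-fold, SIL1 1.86-fold and KAR2 1.39-fold (camera adjusted p = 0.000403, and adjusted p = 0.376 with an estimated correlation). Heat shock genes were higher for 14 of 22 and lower for 3, the same adjusted over the list alone, HSP12 2.75-fold and HSP26 2.58-fold (camera adjusted p = 1.33e-06, and adjusted p = 0.201 with an estimated correlation). Ribosome biogenesis was lower for 32 of 35, 33 adjusted over the list alone, MAK21 by 1.42-fold (camera adjusted p = 1.24e-10, and adjusted p = 0.376 with an estimated correlation).

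For this comparison of AAC with AAP limma called 1814 probe sets, 733 higher and 1081 lower in AAC, with 46 and 1 by 2-fold or more. With each array centred on its median the split was 906 higher and 844 lower, and with the trend on coding length removed 889 higher and 709 lower. The log2 differences correlated with coding length across genes (Spearman rho -0.416). Without AAP anaerobic replicate 1 the count was 1165.

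**Figure D3:**
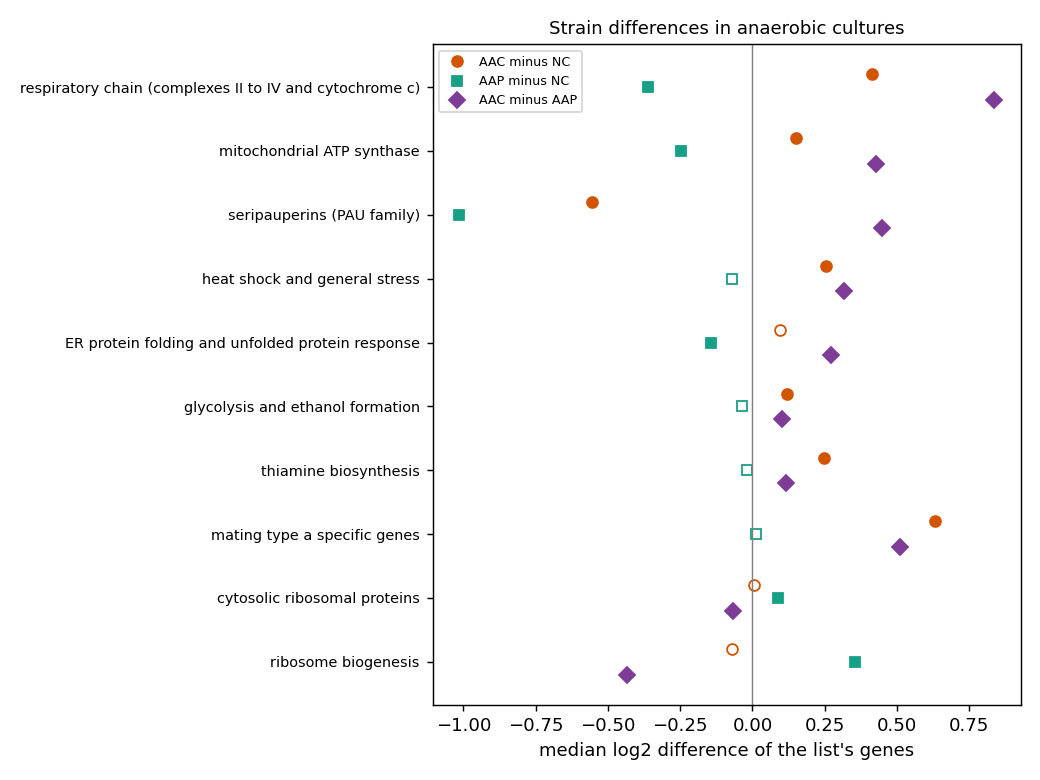
Median log2 difference over the genes of 10 lists for AAC minus NC, AAP minus NC and AAC minus AAP in anaerobic cultures; filled symbols passed the camera test with the preset correlation. For the respiratory chain the medians were 0.42, -0.36 and 0.83.

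Both amylase strains were compared with the same NC arrays. In anaerobic cultures 74 probe sets were higher and 95 lower in both, BIO3, VHT1 and DAK2 among those lower, against 47.7 and 23.4 for independent lists and 0 in 50 simulations of unchanged groups. That 0 decides nothing about the shared controls, since without changed genes hardly any probe set is called in either comparison. Across genes the differences had r = 0.287 and covariance 0.0142, and unchanged groups simulated against shared controls gave r = 0.503 and covariance 0.00393. In aerobic cultures 8 were higher and 2 lower in both, against 0.754 and 0.2996 for independent lists, with r = 0.733 and covariance 0.0228 (simulated 0.496 and 0.00384). Without the array labelled AAP aerobic replicate 3 the aerobic values were 7 and 2, against 1.43 and 3.75 for independent lists, so that fewer were lower in both than expected, with r = 0.157 and covariance 0.00428 (simulated 0.448 and 0.00259). With 3 NC arrays per condition the controls were not divided, since 1 part would hold a single array, so part of an overlap above the expected one can come from the shared controls. The anaerobic balance turned to 123 higher and 104 lower without AAC anaerobic replicate 3. The anaerobic overlap, 169 in both directions together, was 485, 70 and 93 without NC anaerobic replicates 1, 2 and 3, 98 without AAC anaerobic replicate 1, 100 without AAP anaerobic replicate 1 and 258 without the array labelled AAP aerobic replicate 3. The aerobic overlap of 10 was 52 without AAP aerobic replicate 2 and 4 without AAP aerobic replicate 1 or any NC aerobic array. It was 6 without any of the AAC aerobic replicates 1 and 3, the AAC anaerobic replicates 2 and 3, the AAP anaerobic replicates 1 and 2, or the NC anaerobic arrays.

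Whether the oxygen effect differed between strains was tested as an interaction. It differed between AAC and NC for 158 probe sets (92 higher, 66 lower in AAC), between AAP and NC for 687 (441 and 246) and between AAC and AAP for 195 (77 and 118). Without the array labelled AAP aerobic replicate 3 the counts were 667, 545 and 286. With the trend on coding length removed all 3 balances turned, to 70 higher and 90 lower for AAC and NC, 328 and 380 for AAP and NC and 50 and 27 for AAC and AAP. The AAC and AAP balance also turned to 96 and 72 with arrays centred on their medians, and the AAC and NC balance to 61 and 65 with trend and robust settings. Fitted to only the arrays of the groups compared the counts were 582, 308 and 92, the last with 47 higher and 45 lower. The oxygen effect on ER folding genes was lower in AAC than in NC (median log2 difference of the effects -0.29, camera adjusted p = 5.46e-05, and adjusted p = 0.481 with an estimated correlation) and in AAP than in NC (-0.40, camera adjusted p = 8.74e-07, and adjusted p = 0.352 with an estimated correlation; 1.21e-06 without the array labelled AAP aerobic replicate 3). Respiratory chain genes fell less in AAC than in AAP (0.67, camera adjusted p = 2.56e-21, and adjusted p = 0.0312 with an estimated correlation; 2.09e-16 without the array). Ribosome biogenesis transcripts fell less with anaerobic growth in AAC than in NC (0.27, camera adjusted p = 1.75e-06, and adjusted p = 0.528 with an estimated correlation) and differed between AAP and NC (0.50, camera adjusted p = 4.77e-12, and adjusted p = 0.352 with an estimated correlation; 2.60e-13 without the array). The AAC and NC count was 61 to 94 without any 1 of the AAC or NC arrays other than AAC aerobic replicate 2, AAC anaerobic replicate 3 and NC anaerobic replicate 1, and in each of these but that without NC aerobic replicate 3 more were lower than higher. The AAP and NC count was 1194 without AAP aerobic replicate 2 and 1338 without NC anaerobic replicate 1, and 236 to 354 without any 1 of the NC aerobic arrays, NC anaerobic replicates 2 and 3 or AAP anaerobic replicates 1 and 2. The AAC and AAP count was 424 without AAP aerobic replicate 2 and 332 without AAP anaerobic replicate 3, and 69 to 107 without any 1 of AAC aerobic replicates 2 and 3, AAP aerobic replicate 1, AAC anaerobic replicate 2 or AAP anaerobic replicates 1 and 2, each time with more higher than lower.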

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

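The tests of the odd array, of coding length and of DET1, and the second set of random splits, were chosen after the results they bear on had been seen. The first count of other splits for each contrast was planned.

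The oxygen effect differed between strains by a test of the interaction for 158 probe sets between AAC and NC, 687 between AAP and NC and 195 between AAC and AAP. The signed oxygen effect was higher in AAC than in NC for ULI1 (difference of log2 effects 1.57), the zinc transporter ZRT2 (1.11) and the alpha agglutinin SAG1 (1.06), and lower for HES1 (-3.97), PHO84 (-2.65) and the biotin transporter VHT1 (-1.77). HES1 was at background in aerobic NC and PHO84 in anaerobic AAC, so these 2 values are no exact sizes: with the dim values raised to background they were -3.92 and -2.38, which bound the differences from above. In AAP against NC the difference was 1.26 for ILV3 (1.03 without the array labelled AAP aerobic replicate 3), 1.16 for glutamine synthetase GLN1 (1.14 without it) and 1.15 for the uridine permease FUI1 (1.03 without it). It was -2.50 for TMA10 (-2.27 without that array), -1.91 for STF2 (-1.55 without it) and -1.88 for BIO3 (-1.79 without it). Between AAC and AAP the difference was 2.02 for ULI1 (1.81 without the array), 1.94 for FLO11 (1.85 without it) and 1.296 for RGI1 (1.21 without it), and -1.34 for GCV2 (-1.17 without it), -0.88 for CAR2 (-0.82 without it) and -0.79 for GCV1 (-0.69 without it).

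Signal also appeared outside the probe sets tested for S. cerevisiae genes. Fission yeast tpi1, the plasmid's marker, was above NC in aerobic cultures by 2.99 log2 units in AAC (SE 0.467, adjusted p = 0.00228) and by 5.11 in AAP (6.16 without the array labelled AAP aerobic replicate 3). The SE rests on the spread shared by all groups, which that array widens. In anaerobic cultures it was above NC by 3.21 in AAC (adjusted p = 0.000758) and by 5.74 in AAP (adjusted p = 1.51e-08). The low level in NC was not explained by any test here. Among probe sets with no gene in the annotation, RPTR-Sc-J01347-3_at was above NC in AAC by 1.62 log2 units in aerobic and 1.59 in anaerobic cultures. RPTR-Sc-J01347-4_at was above NC in AAC by 1.15 and 1.14. RPTR-Sc-AJ002682-2_s_at, a shared probe set, was above NC in AAP in anaerobic cultures by 3.06 (adjusted p = 9.41e-06). In aerobic cultures, with all arrays as labelled, it did not pass between AAP and NC (log2 difference 0.52, adjusted p = 0.996).

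Each count of changed probe sets was set beside other splits of the same arrays. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split alone reached its count (1 of 10) for the oxygen effect in NC (2763, highest other 0), AAC (2445, highest other 0) and AAP (2110, highest other 0), for AAC minus NC in aerobic cultures (1067, highest other 0), for AAP minus NC in aerobic (11, highest other 0) and anaerobic cultures (1153, highest other 0), and for AAC minus AAP in anaerobic cultures (1814, highest other 2). For AAC minus AAP in aerobic cultures 3 of 10 splits gave as many as the real 218, and the others gave 711 and 565. Both put the array labelled AAP aerobic replicate 3 with 2 AAC arrays, which points to a structure of the arrays. For AAC minus NC in anaerobic cultures 2 of 10 gave as many as the real 660. The other, with 716, put NC anaerobic replicate 1 with AAC anaerobic replicates 1 and 2. That NC array lay further from its group than the other NC anaerobic arrays did. Its Pearson r across genes was 0.9919 and 0.9883 with NC anaerobic replicates 2 and 3, which had 0.99785 with each other, and 0.9886 with AAC anaerobic replicate 1. It was as close to AAP anaerobic replicate 3 (0.9885). The mean r of this NC array was 0.9863 with the AAC and 0.9874 with the AAP anaerobic arrays. For fission yeast tpi1 it read 7.29, against 6.42 and 6.43 in NC anaerobic replicates 2 and 3. No explanation was tested for it.

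For the mean oxygen effect 1 of 100 drawn splits, the real one, reached 3386 (highest other 2674), and in the second draw again 1 of 100 (highest other 2320), so chance can be excluded as the source of that count. For the interactions 4, 5 and 11 of 100 splits reached the real 158 (AAC and NC), 687 (AAP and NC) and 195 (AAC and AAP), with highest others of 1483, 840 and 2027. A second draw was added because the correction of an error in how the splits were drawn had moved shares across 0.05. It gave 6, 1 and 8 of 100, with highest others of 1483, 579 and 2223. The shares for AAC and NC and for AAP and NC thus fell on both sides of 0.05, and neither draw is relied on. For AAC and AAP both draws lay above 0.05. Some of the splits that reached the real count exchanged all strain labels in 1 condition, which turns strain differences into an interaction and points to a structure of the arrays. For AAC and AAP these were 5 in each draw. With all splits of that kind set aside, a step chosen after the counts were seen, the real count was reached by 6 of 90 and 3 of 90 there, by 1 of 93 and 4 of 89 for AAC and NC and by 2 of 90 and 1 of 90 for AAP and NC, the real split included. The shares for AAC and AAP then fell on both sides of 0.05 as well, and for none of the 3 interactions is chance taken as excluded.

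The array labelled AAP aerobic replicate 3 lay apart from AAP aerobic replicates 1 and 2. A swap with an AAC aerobic array needs a partner out of place, and the highest AAC aerobic tpi1 value lay 2.97 log2 units below the lowest of the other AAP arrays. A mixture of AAP with AAC RNA needs tpi1 above the AAC aerobic arrays, and it lay at -0.17 relative to the highest of them, which leaves room for at most 2.08% of the AAP signal over the lowest. On 1814 probe sets called between AAC and AAP in anaerobic cultures, on a scale of 0 for the other AAP aerobic arrays and 1 for the AAC aerobic arrays, it lay at 1.13 (AAC aerobic arrays 0.975 to 1.04), so a single wrong label on an AAC aerobic culture is a candidate explanation. Not all genes lay within the AAC aerobic range as tpi1, DET1 and HES1 did. HAC1 read 9.68 in this array, against 10.41 to 10.47 in the AAC aerobic arrays and 10.07 and 10.25 in AAP aerobic replicates 1 and 2. PDI1 read 10.93, against 11.09 to 11.22 in the AAC aerobic arrays and 10.92 and 10.79 in those replicates. No biological explanation was tested for this array.

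Strain differences in anaerobic cultures followed coding length, with Spearman rho across genes of -0.416 for AAC minus AAP and 0.339 for AAP minus NC, where genes are not independent replicates. With the trend removed, 71.0% of the 1814 calls and 75.1% of the 1153 calls held in the same direction, which argues against a length bias as the whole cause of these differences. For the AAC and AAP interaction 34.4% of 195 calls held, with rho -0.621 before the removal, so a length bias may account for much of that count. A difference between the strains, named by the design, stays open beside it as untested.

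DET1 was lower in AAP than in NC in anaerobic cultures, by 4.87 log2 units on the deposited scale. A loss of the whole region around TPI1 is argued against by the 6 nearest measured neighbours, whose median difference was 0.0147 log2 units (-0.37 to 0.11). The difference was -4.88 after quantile normalization, which decides nothing about the authors' normalization, since it shifted no value by more than 0.216 log2 units and so could not have removed the difference. Genes of like level did not fall with DET1. In anaerobic cultures the median of 128 cytosolic ribosomal protein genes was 11.28 in NC and 11.36 in AAP. These values argue against a normalization that moves probe sets of like level together as the source for DET1. A processing step that acts on single probe sets stays open. A difference confined to DET1 between the strains, or a sequence variant under its probe set, could give the same signal and was not tested. DET1 lies beside TPI1, and the cassette promoters differ too, TPI1 in AAC and TEF1 in AAP. Whether the plasmids bear on the DET1 signal was not tested either.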

How the results depend on the processing

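The fits without the array labelled AAP aerobic replicate 3 for contrasts that do not use it, the removal of the length trend and the list tests without single arrays were chosen after the data were seen. Oxygen effects, in each strain and in the mean, stayed within 1.5 times their counts under every alternative run, with 2363 to 3089 probe sets in NC, 1961 to 2838 in AAC, 1768 to 2303 in AAP and 3214 to 3670 in the mean when 1 array was left out. Quantile normalization, median centring, the filter on dim probe sets and eBayes with trend and robust settings moved no count by more than 1.5 times. Signal over background limits folds of dim genes, which are lower bounds.

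Strain comparisons moved with single arrays. Leaving out 1 array gave 554 to 1650 probe sets for AAC minus NC, 4 to 60 for AAP minus NC and 5 to 1546 for AAC minus AAP in aerobic cultures, and 326 to 1069, 440 to 1749 and 1165 to 2276 in anaerobic cultures. The interactions ranged over 61 to 667 (AAC and NC), 236 to 1338 (AAP and NC) and 69 to 424 (AAC and AAP), and the overlap of the comparisons with NC over 4 to 52 in aerobic and 70 to 485 in anaerobic cultures. The highest values came without the array labelled AAP aerobic replicate 3 for all 6 comparisons but AAP minus NC in aerobic cultures (without AAP aerobic replicate 2). Leaving out an array far from its group lowers the spread that all groups share.

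Fitted to only the arrays of the groups compared, the aerobic counts were 2079 for AAC minus NC, 1 for AAP minus NC and, by limma, 0 for AAC minus AAP (707 at an unadjusted p under 0.05), and the interactions 582, 308 and 92. There 81 named genes passed of the 102 that could be tested. The replicate number as a block gave 140 for AAC minus AAP in aerobic cultures (176 with the length trend removed as well), and for AAC minus NC in aerobic cultures, the other comparison whose same-number pairs all correlated above 0.1, it changed no call of a named gene or list. In the others the same-number pairs did not all do so. Over all groups 18 of 45 same-number pairs correlated above 0.1 and 18 below 0, and 9 of 18 arrays correlated best with their own number. Replicates 1 and 3 of NC and AAC in anaerobic cultures had the highest values (0.645 and 0.459), beside -0.0239 for replicate 2. The length trend removed gave 77 for the AAC and AAP interaction. The cause was not tested. With an estimated correlation between genes 24 of 163 list calls held, and with fry 131. For AAP minus NC in aerobic cultures, the Aft1 iron regulon and ribosome biogenesis turned direction without the array labelled AAP aerobic replicate 3 (camera adjusted p = 0.775 and 0.956). Across single arrays left out, these p ranged from 2.07e-07 to 0.775 and from 3.80e-09 to 0.956, and the iron regulon also missed the threshold without NC aerobic replicate 2 (0.137).

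Of 130 named genes, 1 missed the threshold with trend and robust settings, 5 with the length trend removed, 2 with median centring, 4 with quantile normalization, 5 with the replicate block and 2 without the array labelled AAP aerobic replicate 3, all with their direction kept. Over the checks that left out 1 other array, 1023 kept the threshold and 141 missed it. A pseudocount was not tried, since the table is in log2.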

Other observations

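No test in this part was chosen after its result was seen, and the genes are list members named by the rule. Sterol and heme genes moved in both directions with anaerobic growth in the mean of the strains. Of 25 ergosterol biosynthesis genes 12 rose and 11 fell, the same adjusted over the list alone (camera adjusted p = 0.768). HMG1, an HMG-CoA reductase, fell by 2.29 log2 units and the desaturase ERG5 by 2.06, while HMG2, the other reductase, rose 1.92-fold. Of 8 heme biosynthesis genes 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.304), HEM14 rising 2.22-fold and HEM3 falling 1.63-fold. NDI1, the internal NADH dehydrogenase, fell 5.18-fold and the lactate dehydrogenase DLD1 3.74-fold. Of 13 measured hexose transporter genes 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.491), HXT2 rising 1.71-fold (log2 difference 1.63 in NC, 0.66 in AAP and 0.04 in AAC, where it did not pass) and HXT1 falling 3.19-fold.

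Genes of mating type a and of haploid cells rose with anaerobic growth. All 7 genes specific to mating type a rose in the mean of the strains, also adjusted over the list alone, the a-factor gene MFA2 2.01-fold and the pheromone receptor STE2 1.59-fold (camera adjusted p = 0.00124, and adjusted p = 0.132 with an estimated correlation). Of 12 haploid genes 10 rose, also adjusted over the list alone, the cell cycle inhibitor FAR1 1.57-fold and FUS1 1.64-fold (camera adjusted p = 0.00313, and adjusted p = 0.0680 with an estimated correlation). In anaerobic cultures 5 of the 7 genes specific to mating type a were higher in AAC than in NC, 6 adjusted over the list alone (camera adjusted p = 4.24e-06, and adjusted p = 0.134 with an estimated correlation). In the mean of the strains, degradation genes of the endoplasmic reticulum rose with anaerobic growth for 12 of 16, also adjusted over the list alone, DER1 1.55-fold, which passed in NC and AAC and not in AAP (camera adjusted p = 0.00344, and adjusted p = 0.205 with an estimated correlation). Exocytosis genes rose in that mean for 11 of 16, also adjusted over the list alone, SSO2 1.37-fold (camera adjusted p = 0.00793, and adjusted p = 0.128 with an estimated correlation).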
